A study of Pseudofrankia inefficax with 10 samples.

How the data were processed

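RNA was measured by sequencing in 10 libraries of Pseudofrankia (Frankia) inefficax strain EuI1c, an actinobacterium related to the nitrogen-fixing root nodule symbionts of actinorhizal plants. Per the labels, 5 libraries came from cultures with 0.1 mM sodium selenite and 5 from cultures without it, all kept for 4 days at 30 °C on glucose. The titles number the libraries by batch from 1 to 5, with 1 control and 1 selenite library in each batch. Per the labels' protocols, RNA was extracted on columns, stable RNA was removed with a bacterial rRNA removal kit, and libraries were made by standard Illumina procedures. The labels do not say whether the batches were separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

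The submitters' processing notes name bcl2fastq, with no version in the sources used here. Per the labels' series design text, reads were mapped to the strain's own genome with CLC Genomics software, again without a version. Whether the counting used the strand was not stated in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. The deposited tables give, per the file headers, total and unique read counts for 7263 genes of the chromosome. They also give TPM and RPKM, which the authors' software computed from the same reads per the file headers, and the gene length in bp, also per the file headers. TPM and RPKM were not used for tests, because the deposited counts allow a count model. The lengths of 99.4% of the 7205 protein-coding genes were multiples of 3, so the lengths are coding lengths. The deposited files of batch 5 are named as combined, and what was combined was not stated.

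Of the 7263 genes, 55 carry an RNA number in their locus tag, 3 carry a gene name (rnpB, ssrA and ffs) and 7205 are protein-coding. The files do not pair the other locus tags with names or products. For this reason, none of the 25 gene lists fixed before the data were examined could be applied (0 of 25), and a correction for GC content could not be made. The 55 RNA-numbered genes were left out of library sizes and tests, and their share of reads was tested by itself.

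Total counts per gene were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, and selenite was compared with control by the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main model held all 10 libraries and no batch term. Scaled CPM below are CPM of the reads outside the 55 RNA-numbered genes after TMM scaling, and errors are SD over 5 libraries unless given as SE. The genes to be named were set by rule: the 8 with the largest rise and the 8 with the largest fall past the threshold that moved one way in all 5 batches at an average log2 CPM of at least 4, or the smallest p-values where too few passed, and the members of the longest runs of neighbouring genes. Locus tags are printed for 4 genes and the others are given by position on the chromosome.

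The batch numbers pair the libraries because the titles give them as batches. Deviations from the group means correlated across genes between libraries of the same batch at 0.26, 0.30, 0.14, 0.23 and 0.71 in batches 1 to 5. Computed within batches 1 to 4 alone the values were 0.16, 0.06, -0.05 and 0.07, so most of the shared deviation came from batch 5. Libraries of different batches reached like values, 0.30 for control 4 with selenite 3 over all batches and 0.25 for control 3 with selenite 4 within batches 1 to 4, so the pairing rests on the titles. The batch as a block was an alternative set in advance, and the block in batches 1 to 4 was added after the data had been seen. Other alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, voom in limma 3.58.1 with sample quality weights, other filters, unique reads, the RNA-numbered genes kept, a test against a 1 log2 unit change, and each library and each batch left out.

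The model was tested on simulated data with 200 genes changed by a known factor. For selenite against control in all 10 libraries without the batch, it recovered 0% of 2-fold and 81.5% of 4-fold changes among 3557 and 3529 genes, with 0 and 1 false calls. With the batch block it recovered 55.5% and 92% in the same libraries, with 3 and 13 false calls. In batches 1 to 4 without the block it recovered 33.5% and 80.5%, with 0 false calls. In batches 1 to 4 with the block it recovered 62.5% of 2-fold changes among 3585 genes and 86% of 4-fold changes among 3607 genes, with 5 and 10 false calls. Apart from the known changes and library size, each simulated mean was set by the batch alone, with the dispersions of the block model. This favours the block by construction, while the real libraries of a batch hardly shared deviations in batches 1 to 4. The rates therefore do not measure the gain from the block in these data. Shares of single measures were compared by exact permutation of the labels over all 252 splits. All 20 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.13 to 24.3, so each library was counted as 1 replicate. Plots were drawn with matplotlib 3.10.9.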

Results

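The series compared the transcriptome of Pseudofrankia inefficax EuI1c grown with 0.1 mM sodium selenite, a toxic oxyanion of selenium, with that of cultures without it. Mapped reads were calculated from the deposited counts, gene lengths and RPKM. The control libraries of batches 1 to 5 held 11810913, 13785641, 17427813, 17161491 and 25089159 mapped reads. The selenite libraries held 16836789, 13092026, 8197275, 13330346 and 38487625. Most reads belonged to stable RNA, and protein-coding genes received 174634 to 483393 reads per library, a median of 4 to 16 reads per gene. Between 129 and 1723 genes per library had 0 reads. The low-count filter left 3728 genes for the main test.

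Stable RNA made up nearly all reads in both groups despite the depletion step. The 55 RNA-numbered genes took 97.3% ± 1.12 of the reads in genes in control (SD, n = 5) and 97.0% ± 1.46 with selenite (SD, n = 5). The difference of -0.26 percentage points was within the spread (two-sided exact permutation test, p = 0.762; exact sign-flip test within batches, p = 0.625), and selenite was higher in 2 of 5 batches. Its sign turned without control 5 (0.163 points) or without selenite 4 (0.172 points). Nearly all of these reads lay in 9 genes of 1494, 3109 and 117 bp, which form 3 clusters with 1 gene of each length. The clusters lie at 1247381 to 1252588 and 2108852 to 2114047 on the plus strand and at 5787219 to 5792429 on the minus strand. These lengths and their order are those of bacterial rRNA operons, but the files do not name the genes. The other 46 RNA-numbered genes were 71 to 90 bp long.

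Among the remaining reads, 2 small RNAs dominated. The transfer-messenger RNA ssrA, which rescues stalled ribosomes (7396664 to 7397035, minus strand), took 20.1% ± 3.20 of the reads outside the RNA-numbered genes in control and 18.5% ± 4.00 with selenite (SD, n = 5 each). The RNase P RNA rnpB, which matures tRNA (3317309 to 3317728, plus strand), took 4.01% ± 0.82 and 5.06% ± 3.33 (SD, n = 5 each). The signal recognition particle RNA ffs (8389266 to 8389357, plus strand) took 0.0617% ± 0.0491 and 0.0315% ± 0.0201 (SD, n = 5 each). None of the 3 passed the edgeR test, with log2 fold changes of -0.15 (SE 0.36) for ssrA, 0.35 (SE 0.43) for rnpB and -0.85 (SE 0.49) for ffs, each at an adjusted p of 1.00. For rnpB the sign rested on selenite 5, without which the log2 fold change was -0.10. For ssrA the sign turned without batch 3, to 0.027. Its log2 ratios in batches 1 and 5 were 0.14 and 0.85. Without batch 5 the log2 fold change of ssrA was -0.38 (SE 0.13, edgeR adjusted p = 0.331). For ffs the log2 fold change was -0.43 without control 5 and -0.32 without batch 5, and its log2 ratio in batch 2 was 0.65.

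In 3 examples among the most abundant protein-coding genes, the group means differed by less than the SD over 5 libraries. The gene at 174270 to 175889 on the minus strand had the highest mean over batches 1 to 4, with 14840 ± 5349 scaled CPM in control and 14576 ± 4482 with selenite (SD, n = 5 each). Of the 21 most abundant protein-coding genes, 6 lay between 7602709 and 7679777. The highest of these 6, at 7666082 to 7667275 on the minus strand, had 10565 ± 4782 scaled CPM in control and 14034 ± 7235 with selenite (SD, n = 5 each). Its neighbour at 7667347 to 7669440 on the same strand had 9067 ± 3683 and 10902 ± 5655 (SD, n = 5 each). Over batches 1 to 4 the means of these 3 genes were 16852, 14728 and 11833 scaled CPM. These lay above both group means of each gene, so the levels in batch 5 were lower. The SD includes batch 5, and the comparison leaves out the pairing by batch. It therefore does not test whether selenite changed these genes within batches.

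The 2 libraries of batch 5 stood apart from the other 8, whatever their group. Spearman's rho across genes was 0.837 to 0.919 between any 2 libraries of batches 1 to 4 and 0.570 to 0.672 between a library of batch 5 and any of these. The 2 libraries of batch 5 correlated with each other at 0.747. The first principal component took 49.0% of the variance, with control 5 at 45.3 and selenite 5 at 53.1 and the other 8 libraries from -24.5 to -7.54. The second took 13.3% and set selenite 3, the library with the fewest reads in protein-coding genes, at -35.5 apart from the other 9, which lay from -9.60 to 11.3. In batch 5 the reads were spread more evenly over the protein-coding genes, and followed the coding length more closely, with rho across genes of 0.595 in control and 0.594 with selenite against 0.260 to 0.326 elsewhere. Genes are not independent replicates, so these values describe the libraries only.

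**Figure D1:**
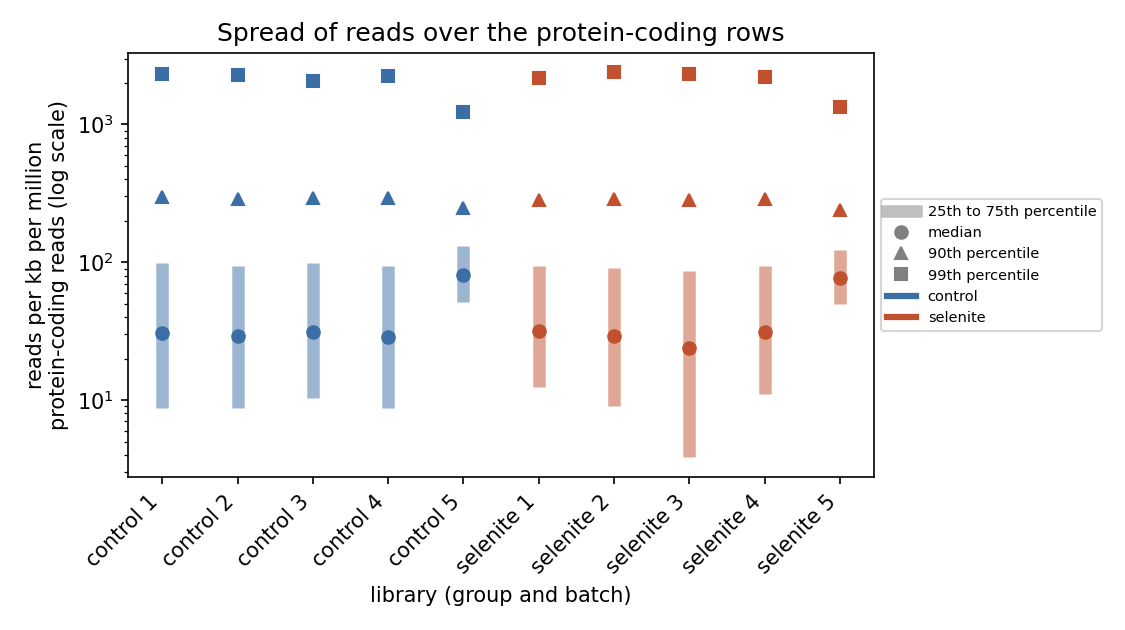
Reads per kb of coding length, scaled to the same total of protein-coding reads, on a log axis in the 10 libraries; bars span the 25th to 75th percentile of the genes, and circles, triangles and squares mark the median and the 90th and 99th percentiles. The median lies at 80.7 in control 5 and 76.3 in selenite 5, and at most at 31.9 in the other 8 libraries.

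The comparison asked which transcripts differ under selenite stress. No gene passed in the main model of all 10 libraries without the batch, with 0 of 3728 (edgeR; 133 at an unadjusted p under 0.05), and 1 passed with the batch as a block, an alternative set in advance. In a model added after the data had been seen, which set each selenite library of batches 1 to 4 against the control of its own batch, 6 genes were higher with selenite by 1.53 to 2.52 times and 10 were lower by 1.65 to 3.00 times. The gene with the greatest rise, FraEuI1c_6399 (7865505 to 7866257, plus strand), went from 79.9 ± 15.2 to 200 ± 88.7 scaled CPM over all batches (SD, n = 5 each). The gene with the greatest fall, FraEuI1c_1999 (2448522 to 2448938, minus strand), went from 92.1 ± 49.5 to 30.6 ± 21.1 (SD, n = 5 each). Called in 3 of 4 edgeR models was the fall of FraEuI1c_0552 (689168 to 690421, plus strand), from 793 ± 482 to 360 ± 199 scaled CPM (SD, n = 5 each). The files pair none of these locus tags with a gene name or product.

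How many genes passed depended on the batch. In the main edgeR model of all 10 libraries without the batch, 0 of 3728 genes passed the threshold, and 133 had an unadjusted p under 0.05 where chance gives 186. DESeq2 and voom without the batch also called 0, with 158 and 312 genes at an unadjusted p under 0.05. DESeq2 judged 7149 genes, so its count lay below the share of 0.05 given by chance. The count of voom, on 3728 genes, thus lay above the 186 given by chance. The biological coefficient of variation was 37.6% in the main edgeR model. With the batch as a block it was 22.1%, 324 genes had an unadjusted p under 0.05, and 1 gene, FraEuI1c_0552, passed (log2 fold change -1.14, SE 0.17, edgeR adjusted p = 0.0211). The edgeR call of FraEuI1c_0552 with the block held without batch 1 (adjusted p = 0.00833) and ended without batch 2, 3 or 4 (adjusted p = 0.350, 0.0593 and 0.0796), while its log2 fold change stayed between -1.29 and -1.08. These models called 4, 0, 0 and 1 lower genes. With the block in all 10 libraries, added after the data had been seen, DESeq2 called 2 higher and 9 lower genes and voom 11 and 14. Without batch 5 and without the block, 1 gene was higher and 3 were lower. With the block in batches 1 to 4, the model added after the data had been seen, the variation was 17.5%, 6 genes were higher and 10 lower among 3785, and 388 had an unadjusted p under 0.05 where chance gives 189. A further batch left out of it gave 1 higher and 5 lower without batch 1, 0 and 2 without batch 2, 22 and 32 without batch 3, and 10 and 12 without batch 4. Of these 6, 2, 54 and 22 genes, 6, 2, 14 and 10 were among the 16.

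In that model FraEuI1c_6399 rose by 1.34 on the log2 scale (SE 0.24, edgeR adjusted p = 0.0134). Its log2 ratios within batches 1 to 5 were 1.74, 1.62, 1.92, 0.15 and 0.58, so it was higher in 5 of 5 batches and least so in batch 4. The naming rule required such agreement of this gene and of the next one named, and 404 of the 3728 tested genes had it. FraEuI1c_2225 (2721933 to 2726552, plus strand) rose by 0.82 (SE 0.19, edgeR adjusted p = 0.0445), from 162 ± 25.4 to 292 ± 66.1 scaled CPM (SD, n = 5 each), and was higher in 5 of 5 batches. Over all 10 libraries without the batch the log2 fold changes of these genes were 1.31 (SE 0.30) and 0.84 (SE 0.22), each at an edgeR adjusted p of 1.00. The other 4 higher genes lay at 19811 to 20680, 7312706 to 7313002 and 8558223 to 8558765 on the plus strand and at 1020637 to 1024374 on the minus strand, with log2 fold changes of 0.83, 0.74, 0.86 and 0.62. The genes at 19811 and 8558223 went the other way in batch 5, with log2 ratios of -0.48 and -0.69.

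FraEuI1c_0552 fell by 1.10 on the log2 scale in batches 1 to 4 with the block (SE 0.15, edgeR adjusted p = 0.000204). This gene lies outside the naming rule and was chosen after its values were seen. It was lower with selenite in 5 of 5 batches, with log2 ratios of -0.65, -1.21, -1.33, -1.16 and -1.68, although both batch 5 values, 63.5 in control and 19.2 with selenite, lay far below those of the other batches. FraEuI1c_1999 fell by 1.58 (SE 0.31, edgeR adjusted p = 0.0134) and was lower in 5 of 5 batches, with log2 ratios from -2.90 to -0.89. The naming rule required this agreement. Its selenite levels were low, with 17.2 scaled CPM in selenite 1 and 19.9 in selenite 3, the library with the fewest protein-coding reads. The largest ratio, in batch 3, thus rests on few reads.

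**Figure D2:**
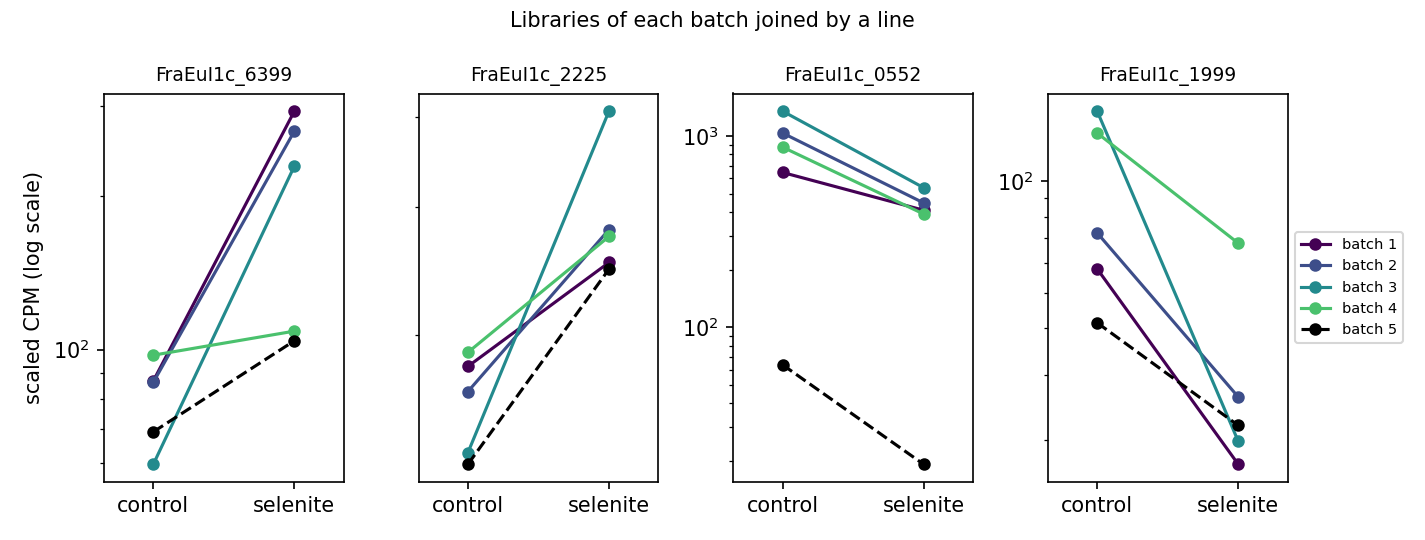
Scaled CPM on log axes for the 4 genes named by locus tag in the control and selenite library of each batch, joined by a line, with batch 5 dashed. The axis range differs between panels. Each gene moves one way in all 5 batches, which the naming rule required of all but FraEuI1c_0552, itself chosen after its values were seen.

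Several of the lower genes were neighbours on 1 strand. Groups were found by extending each gene past the threshold over same-strand neighbours of the same direction with an unadjusted p under 0.05. The like direction within a group was thus set by the search. Most genes past the threshold had no such neighbour. The gene next to FraEuI1c_0552, at 688587 to 689171, overlaps its start and fell by 1.39 (SE 0.22, edgeR adjusted p = 0.0134), from 1036 ± 704 to 380 ± 211 scaled CPM (SD, n = 5 each). Between 8060256 and 8062596 on the plus strand, 3 consecutive genes had log2 fold changes of -1.28 to -1.09 in batches 1 to 4 with the block, and 2 of them passed. Their falls were smallest in batch 1, with log2 ratios of -0.21, -0.27 and -0.66. Between 8771380 and 8773106 on the plus strand, 3 consecutive genes had values of -1.20 to -1.07, and 1 of them passed (edgeR adjusted p = 0.0115). The remaining lower genes lay at 1382092 to 1382361 on the plus strand and at 4917633 to 4918607, 7761578 to 7764031 and 8177662 to 8178717 on the minus strand, with log2 fold changes of -0.73, -0.80, -1.13 and -0.80. The count of runs of at least 4 neighbouring genes past the threshold was 0 in the main model, with the block in all 10 libraries, and in batches 1 to 4 with and without it. The main model and the block in all 10 libraries called fewer than 4 genes, so no run was possible there.

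Batch 5 did not enter the model that gave the 16 genes and served as a check of their direction, added after the data had been seen. In batch 5, 13 of the 16 had the same direction, 4 of the 6 higher and 9 of the 10 lower, where 8.11 are given by chance (one-sided exact test, p = 0.0121, which treats genes as independent). The exception among the lower genes was that at 1382092, with a log2 ratio of 0.24. Some directions rest on low levels in batch 5. The gene at 688587, in the same direction, had 27.6 scaled CPM in control 5 and 21.9 in selenite 5. The gene at 8558223, in the other direction, had 35.9 and 21.9. An estimated 47.2% and 46.3% of the protein-coding reads in these 2 libraries were proportional to coding length. The test takes account of neither limit. The genes of the naming rule, 8 higher and 8 lower, had log2 fold changes of 0.63 to 1.31 and -1.66 to -0.75 in the main model, where none passed, and 6 of them were among the 16.

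**Figure D3:**
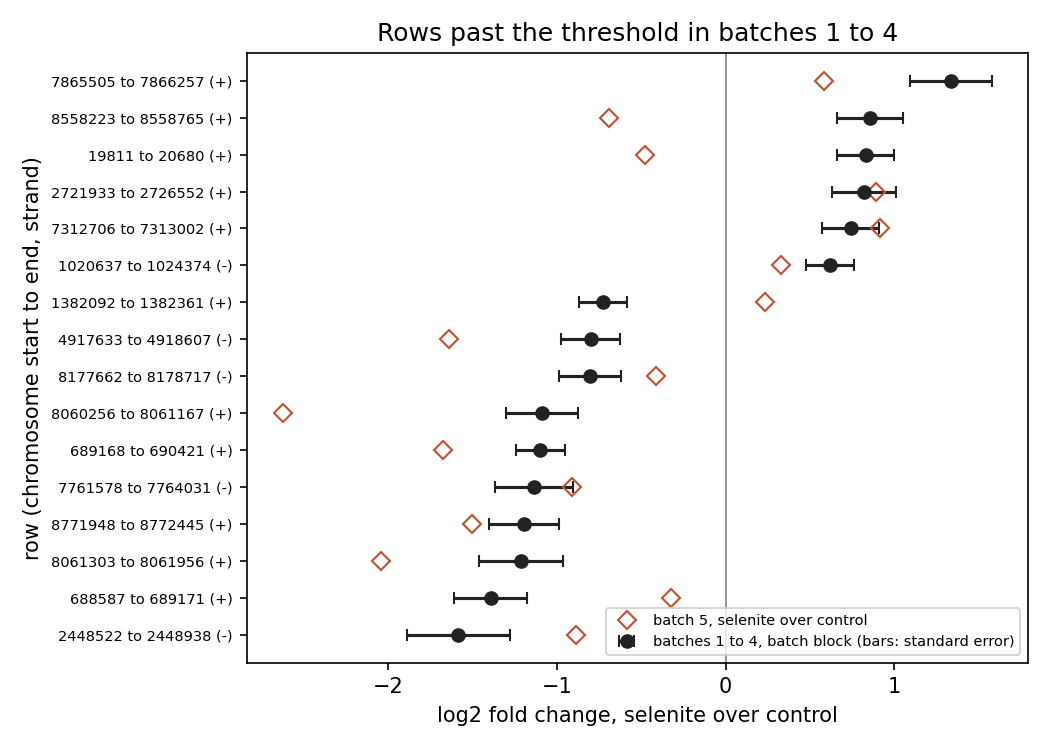
Log2 fold change of selenite over control for the 16 genes past the threshold in batches 1 to 4 with the batch block (filled circles, bars are SE) and the log2 ratio of the batch 5 libraries (open diamonds), with chromosome positions and strand on the vertical axis. In 13 of the 16 genes the batch 5 value lies on the same side of 0.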

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

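The tests of even read spread and of depth were chosen only after the results were seen. Of 80 checks for a library far from the others of its group, 14 found one, and 11 of the 14 concerned batch 5. Chance would give about 4 on average. The checks are not independent, since several measure the same evenness of reads, so the flags do not count separate results.

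In selenite 5 the mapped reads numbered 38487625, against 8197275 to 16836789 in the other selenite libraries. In control 5, the copy of the 3109 bp RNA gene at 5787444 to 5790552 took 0.133% of the reads of its 3 copies (Wilson 95% interval 0.131 to 0.135, counting error only), against 0.0289 to 0.0372% in the other controls. Most of the 25962 reads credited to this copy in control 5 matched several places, so the share may depend on how such reads were assigned. The 46 short RNA-numbered genes held 5588 reads in control 5, against 94 to 694. The correlation of reads with coding length was 0.595 in control 5 and 0.594 in selenite 5. The 90th percentile of reads per kb was 3.05 times the median in control 5, against 9.36 to 10.3 times in the other controls. A component of reads proportional to coding length was estimated at 47.2% of protein-coding reads in control 5 and 46.3% in selenite 5, against at most 2.95% in the other 8 libraries.

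The pattern that batch 5 stands apart was weighed against 3 technical explanations. Lower depth is argued against, because each library of batches 1 to 4, resampled to 260831 reads (selenite 3 to its own 212796, fewer than in batch 5), still had a median rho with the others that was higher by at least 0.192. A sum of the other libraries is argued against, because the genes with the fewest reads held 14.6 and 15.7 times the reads that the best such sum predicted. Reads spread evenly over the chromosome, as genomic DNA could give, stay open, since the smaller estimate of 46.3% lies under the 50% set for this explanation and above the 25% that would have excluded it. Batch 5 holds both groups, and no biological explanation was tested.

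Single genes also had a library far from the others of its group. The gene at 2721933 had 407 scaled CPM in selenite 3 and the gene at 2448522 had 67.9 in selenite 4. The gene at 2371344 had 390 in control 5, the gene at 689168 had 19.2 in selenite 5, and the gene at 1382092 had 395 in control 5. The gene at 8061303 had 198 in selenite 1.

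Whether the number of called genes exceeds that of other splits of the libraries was asked for each edgeR model. For all 10 libraries without the batch the real split gave 0 genes and the highest of the others 11. All 100 of 100 splits reach a count of 0 by construction, so this comparison decides nothing. In batches 1 to 4 without the block the real split gave 4 genes, 4 of 35 splits gave as many, and the highest, 54 genes, came from batches 1 and 2 against batches 3 and 4, which points to a structure of the samples. With the block, the splits that swap libraries within batches are too few for a share under 0.05. There the real split gave 1 gene in all 10 libraries and the highest of the other splits 0 (1 of 16), and in batches 1 to 4 it gave 16 and the highest other 0 (1 of 8).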

How the results depend on the processing

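The block in batches 1 to 4, DESeq2 and voom with the block, and the model without rnpB, ssrA and ffs were chosen after the data had been seen. The counts of 0 genes higher and 0 lower stayed at 0 under RLE and upper quartile scaling, DESeq2, voom, no filter, a CPM filter, unique reads, the RNA-numbered genes kept, the test against a size, and without rnpB, ssrA and ffs. With the batch block, 0 were higher and 1 lower. With the block in batches 1 to 4, 6 were higher and 10 lower. With DESeq2 and the block, 2 were higher and 9 lower, and 8 of these 11 were among the 16. With voom and the block, 11 were higher and 14 lower, and 14 of these 25 were among the 16. In the main model, without the block, with a library or a batch left out, higher genes numbered 0 to 1 and lower genes 0 to 3, where the highest counts came without batch 5. In simulations, 2-fold changes were recovered at 0% in all 10 libraries without the block, 33.5% in batches 1 to 4 without it and 55.5% in all 10 with it. Those simulations gave the libraries of a batch a shared mean, which favours the block. Runs of neighbouring genes stayed at 0 under each alternative for which they were counted, which leaves out the block models with a further batch left out. Most alternatives called too few genes for a run, so only those with more calls could have shown one. The stable RNA difference ranged from -0.79 to 0.172 points with libraries left out, positive without control 5 (0.163) or selenite 4 (0.172). The log2 fold change of rnpB turned to -0.12 under voom and -0.16 with the block in batches 1 to 4, and ranged from -0.12 to 0.54 with libraries left out (-0.10 without selenite 5, -0.12 without batch 5). That of ssrA ranged from -0.38 to 0.027, positive without batch 3. The cause was not tested. Of the other values of single genes under the alternatives, 783 kept direction and side of the threshold and 47 kept direction and newly passed it. The GC correction and the gene list tests were not run. The low-count filter left 3728 genes for the main test, and genes under it were not judged.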

Other observations

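Of the tests below, only that of neighbouring genes was chosen before its result was seen.

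The ratio of reads in the 1494 bp RNA genes to those in the 3109 bp RNA genes was lower with selenite in 5 of 5 batches. It was 0.252 ± 0.038 in control and 0.205 ± 0.040 with selenite (SD, n = 5 each; two-sided exact permutation test, p = 0.0873, adjusted p = 0.175 over 2 measures). Within batches the selenite ratio was 0.706 to 0.921 times the control ratio (exact sign-flip test, p = 0.0625, the smallest that 5 pairs allow). A difference in the strength of depletion, as seen in the share of other reads, may account for it and stays open. Over all 10 libraries the log2 difference at equal share was -0.308 with the batch as a block and -0.301 without it. The mean log2 difference within batches was -0.302, so equal share did not shrink it there. In SE it was -4.18 with the block (threshold 3.18 SE) and -1.83 without it. In batches 1 to 4 it was -3.50 SE with the block (threshold 4.30 SE) and -1.08 SE without it, which does not settle the question. The group-centred ratio correlated with that share at r = -0.063 over all 10 libraries (permutation p = 0.862) and at -0.599 in batches 1 to 4 (exact permutation p = 0.155). Uneven removal of the 2 RNA lengths, RNA quality and an effect of selenite on the RNA itself were not tested.

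The copy of the 1494 bp gene at 5790936 to 5792429 took 2.43% ± 1.37 of the reads of its 3 copies in control and 1.51% ± 0.82 with selenite (SD, n = 5 each; two-sided exact permutation test, p = 0.222). It was lower with selenite in 5 of 5 batches, at 0.457 to 0.723 times the control (exact sign-flip test, p = 0.0625). Most reads credited to this copy also matched other places. In control 1 it was credited with 100570 reads, while all genes together held 276974 unique reads. Reads outside the RNA-numbered genes, nearly all unique, numbered 276202 in control 1. The share may thus reflect how reads with several matches were assigned, which was not tested.

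Close neighbours on 1 strand tended to have like log2 fold changes. Over 601 pairs at most 50 bp apart in batches 1 to 4, the correlation across genes was 0.352, against 0.127 for 911 neighbouring pairs on opposite strands. The latter pairs had no limit of distance, so this contrast does not separate strand from distance. The hypothesis that shared transcripts differ between libraries whatever their group stays open. The real split gave the highest correlation, 1 of 8 splits, the outcome set to exclude it, but the next was 0.285, and 8 splits are too few for a share under 0.05.

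The RNA-numbered gene at 7689905 to 7689980 held 1218 reads in control 5 and 13 to 225 in the other 9 libraries.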
